A study of Homo sapiens with 10 samples.

How the data were processed

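The series measured polyadenylated RNA in 10 samples of RPE p53-/- cells, 5 parental and 5 with CCAR1 knocked out, grown in the same medium. Genotype and replicate number come from the sample titles. The labels do not say whether replicates were separate cultures or the knockout cells a single clone, so p-values measure the spread between these samples, which may be technical, and a difference between genotypes can include any difference between these cell populations. Per the labels' protocols, libraries were made with a poly(A) enrichment and NEBNext Ultra II kit and sequenced on a NovaSeq. Strand-specific counting is not given in the sources used here, so overlapping and antisense genes are uncertain.

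The deposited table gives an estimated count (expected count) per gene and library, not normalized for depth or length. Per the submitters' processing notes the authors used kallisto 0.48.0 with hg38; the annotation release and the step from transcripts to genes are not given in the sources used here. The table holds genes, so the transcript-level test planned before the data were examined was not run and splicing itself was not analysed here. Kallisto divides reads that fit several transcripts by likelihood, so close paralogs can exchange counts.

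Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with genotype as the group, which left 18979 of 62700 genes. Library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion and genotype as its term was fitted in edgeR 4.0.16 (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are in CPM, counts per 1e6 of the scaled library size. Standard errors were computed from the coefficient and its F statistic. The 37 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3 and a preset correlation of 0.01, two-sided, adjusted over the lists, with an estimated correlation and fry beside it. No list passed with an estimated correlation (smallest adjusted p = 0.132), and 27 passed fry. Single genes were also tested by an exact two-sided permutation of log2 CPM. Gene positions are from a GENCODE annotation of the GRCh38 assembly (hg38), matched by gene ID without version for 95.1% of the genes tested.

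Genes were named by a rule fixed before the data were examined: CCAR1, CCAR2 and FANCA; every Fanconi anemia core member past 0.05; up to 4 members with the smallest adjusted p from the homologous recombination, splicing and camera-passing lists, with 2 in each direction where there were as many; and the 8 largest changes each way among named, non-pseudogene genes past 0.05 with at least 2 CPM in either genotype and no overlap between the genotypes.

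Library totals (in 1e6 counts, M) ran from 52.6 to 65.2 M in replicates 1 to 3 and from 320.6 to 385.4 M in replicates 4 and 5, and this split was found in the data. Within a genotype and depth, pairs of libraries differed by more than sampling noise (chi-square per gene 7.87 to 30.4), so none was merged. The common biological coefficient of variation was 0.310, and 0.0698 with depth as a term.

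Pairing was checked before the fits were compared. Same-numbered samples deviated together from their group means, with correlations across genes of 0.640, 0.584, 0.606, 0.899 and 0.894, which by the rule set for this check pairs the samples. The pairing follows the split into shallow and deep libraries: other numbers of the same depth correlated at 0.594 to 0.901, samples of different depth at -0.776 to -0.725, and within a depth same-numbered samples at -0.0604 to -0.00521. The shallow and deep libraries also differ in transcripts of other tissues and could be separate runs or library batches, which the labels do not say, and what makes them differ was not tested. The replicate block is therefore printed beside the results given where it changes a call or moves a count by over 1.5 times.

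On counts simulated from these libraries' means for 18979 genes, with 50 genes changed at each size for the knockout against parental comparison, the fit recovered 0% of genes changed 1.2-fold, 44% at 1.5-fold, 84% at 2-fold and 88% at 4-fold with 0 false calls; the block recovered 42%, 78%, 94% and 94% with 14 false calls. Alternatives planned before the data were examined were DESeq2 size factors, library size only, no filter on low counts, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, no robust step, the replicate block, and each library left out. Added afterwards were depth (shallow or deep) as a term, each depth alone, the deep libraries thinned to 52.6 M, and the median of each chromosome removed from the knockout libraries. The rule for naming genes was applied to the letter after a looser form had been run and values seen. An antisense gene and a pseudogene were removed from the protocadherin sums after a first run, which left the conclusion as it was. The values of some genes are not reported here. Figures were drawn with matplotlib 3.10.9.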

Results

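CCAR1, a cell cycle and apoptosis regulator described in the series title as a splicing factor of the Fanconi anemia/BRCA pathway, was disrupted in RPE cells without p53, a human line derived from retinal pigment epithelium. Polyadenylated RNA was sequenced from 5 parental and 5 CCAR1 knockout samples to ask what the knockout changes across the genome. Estimated counts were given for 62700 genes. Replicates 1 to 3 of each genotype held 52.6 to 65.2 M counts (M, 1e6) per library and replicates 4 and 5 held 320.6 to 385.4 M. These are called the 6 shallow and 4 deep libraries here. Of the variance in log2 CPM, 52.8% lay on a principal component that parted the shallow from the deep libraries, and 34% on a component that parted the genotypes. The shallow libraries of both genotypes also held skeletal muscle, erythroid and liver transcripts, with a summed level of 725.1 to 1168 CPM against 19.5 and 20.9 CPM in the deep parental and 37.7 and 38.5 CPM in the deep knockout libraries. Both genotypes have 3 shallow and 2 deep libraries. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18979 genes, and those of gene lists from camera over 37 lists. Every mean ± SD has n = 5, and these SDs include the difference between shallow and deep libraries.

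The targeted gene, CCAR1 (ENSG00000060339.14, chromosome 10, 68721012 to 68792377, hg38), was at 148 ± 23.6 CPM in parental and 106 ± 18.5 CPM in knockout cells, which is 71.5% of the parental level. Its log2 fold change was -0.48 with a standard error of 0.14 (edgeR adjusted p = 0.0201), and the exact two-sided permutation p of log2 CPM was 0.0238. The fold change was -0.51 in the shallow libraries and -0.48 in the deep ones, and each knockout library lay below the parental libraries of its depth, although the pooled ranges of 88.5 to 126 and 125 to 173 CPM met. The call was lost without parental replicate 5 (log2 fold change -0.42, edgeR adjusted p = 0.0504), with library size only (-0.42, adjusted p = 0.0525) and with the median of chromosome 10 subtracted (-0.31, adjusted p = 0.121). It was kept with the replicate block (-0.49, edgeR adjusted p = 2.16e-06) and with depth as a term (-0.49, 1.3e-08). Counts per gene do not show whether the remaining transcripts carry the edit. CCAR2, the paralog of CCAR1, was at 131 ± 8.45 and 117 ± 11.1 CPM, with edgeR adjusted p = 0.140 and, with the replicate number as a block, 0.00535.

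Several genes of the Fanconi anemia core complex, which ubiquitinates the FANCD2 and FANCI pair at DNA crosslinks, were lower in knockout cells. FANCA (ENSG00000187741.16, chromosome 16, 89737549 to 89816657), a core complex subunit, fell from 81.6 ± 2.26 to 50.05 ± 2.10 CPM, 61.4% of the parental level (log2 fold change -0.70, standard error 0.053, edgeR adjusted p = 3.84e-06). The ranges of 79.0 to 83.8 and 48.7 to 53.8 CPM were apart, and the exact two-sided permutation p was 0.00794, the smallest that 252 arrangements can give. FANCA's fold change was -0.72 in the shallow and -0.71 in the deep libraries. FANCI fell from 149 ± 23.3 to 90.4 ± 17.97 CPM, FANCE, a core subunit encoded on chromosome 6, from 20.3 ± 1.71 to 11.5 ± 1.80 CPM, and UBE2T, the E2 enzyme of the complex, from 40.2 ± 2.02 to 29.6 ± 2.51 CPM. The E3 ligase FANCL fell from 30.6 ± 4.91 to 21.3 ± 4.28 CPM and FANCC from 18.5 ± 1.83 to 14.9 ± 0.918 CPM, while FAAP24, on chromosome 19, rose from 6.84 ± 0.407 to 8.30 ± 0.284 CPM. FAAP24 went from a log2 fold change of 0.28 to 0.11 with the chromosome median subtracted, which ended its call (edgeR adjusted p = 0.282), as did leaving out the filter on low counts (0.106). FANCC lost its call with library size only (0.0507) and with no filter (0.0649). FANCL's edgeR adjusted p of 0.0217 became 0.0524 without parental replicate 4 and 0.0544 without parental replicate 5. With the replicate block the edgeR adjusted p was 0.00142 for FAAP24, 2.13e-04 for FANCC and 4.7e-06 for FANCL. Across the 16 measured members of this list, 1 rose, 6 fell and 9 did not pass, and 1 rose and 7 fell when adjusted over the list alone. With the replicate block 3 rose and 9 fell, in a fit that called 11619 of all 18979 genes. FANCB and FAAP100 were among those that fell and FAAP20 among those that rose (edgeR adjusted p = 0.00151, 1.13e-04 and 3.05e-04, against 0.350, 0.0626 and 0.193 without the block). With the chromosome median subtracted the log2 fold change of FAAP100, on chromosome 17, went from -0.28 to -2.28e-04. Its edgeR adjusted p was then 0.942 with depth as a term. The list's median log2 fold change was -0.23, with -0.25 in the shallow and -0.24 in the deep libraries. The list as a whole did not pass (camera adjusted p = 0.0726). With the block its camera adjusted p was 0.0487, and adjusted p = 0.387 with the block and an estimated correlation.

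**Figure D1:**
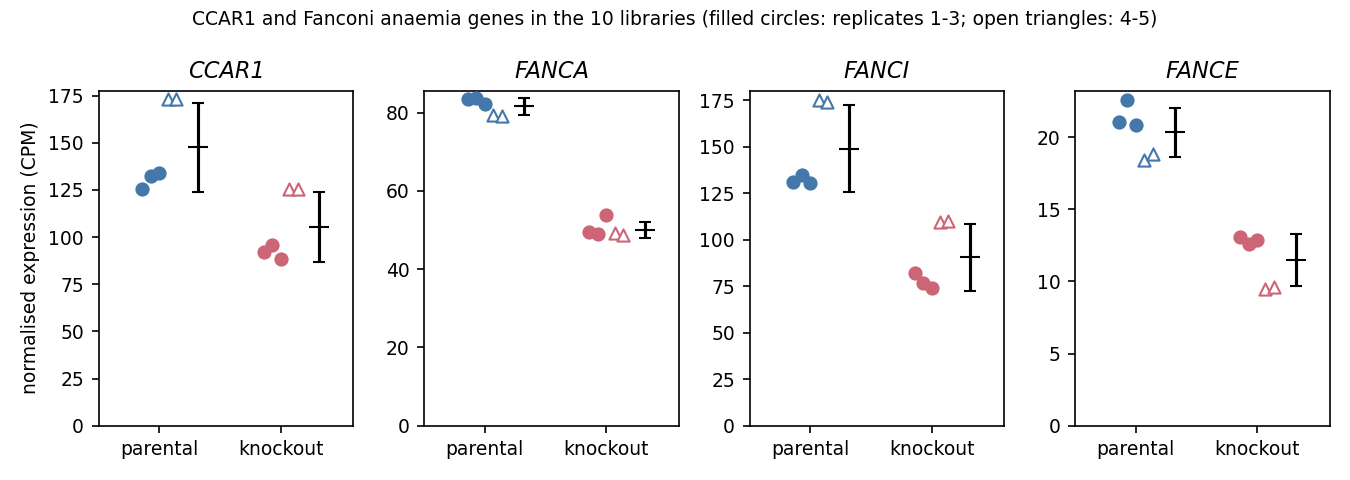
Normalised expression (CPM, linear axis from 0) of CCAR1, FANCA, FANCI and FANCE in each library; filled circles are the shallow and open triangles the deep libraries, and the black bars show the mean ± SD of 5 libraries. FANCA ran from 79.0 to 83.8 CPM in parental and from 48.7 to 53.8 CPM in knockout libraries.

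Among 33 genes that act downstream of this complex and in homologous recombination, 1 rose, 5 fell and 27 did not pass. This is a smaller share called than the 36.6% of all genes tested. Adjusted over the list alone, 1 rose and 2 fell. RAD51D, encoded on chromosome 17, fell from 31.7 ± 1.03 to 19.9 ± 1.03 CPM (edgeR adjusted p = 9.52e-06). RAD54L, a DNA motor protein, fell from 68.6 ± 2.30 to 51.6 ± 1.42 CPM, and RAD51B rose from 4.33 ± 0.305 to 5.51 ± 0.607 CPM. BRCA1 (chromosome 17, 43044295 to 43170245), which was chosen after its values were seen, was at 103 ± 19.9 and 68.6 ± 16.98 CPM (log2 fold change -0.58, standard error 0.18, edgeR adjusted p = 0.0293). The list's median log2 fold change was -0.15, with -0.17 in the shallow and -0.16 in the deep libraries, and it did not pass (camera adjusted p = 0.0726). With the replicate block 5 members rose and 19 fell (camera adjusted p = 0.0196, and adjusted p = 0.563 with the block and an estimated correlation). The unblocked list test passed without parental replicate 2 (adjusted p = 0.0448), knockout replicate 4 (0.0301) or knockout replicate 5 (0.0292), while over all libraries with an estimated correlation its adjusted p was 0.692.

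Over the whole transcriptome, 3741 genes were higher and 3198 lower in knockout cells, which is 36.6% of the genes tested. The change was at least 2-fold for 2004 genes, with 1417 higher and 587 lower. The replicate block, which takes up the difference between the shallow and deep libraries, gave 5906 higher and 5713 lower genes. The shallow libraries alone gave 4980 and 4931, and the deep libraries alone 7775 and 7545 of 26859 genes tested. The counts over all genes, 11619 of 18979 with the block, are the background for the counts of list members. In the core spliceosome and mitotic lists given below, 11 of 51 and 13 of 46 genes were called without the block, a smaller share than 36.6%. Across 18461 genes fitted in both, the log2 fold changes of the shallow and the deep libraries correlated with r = 0.875. The knockout and parental ranges did not overlap for 5812 genes, or 30.6%. Chance would give 0.794% if all 10 libraries were exchangeable, which the shallow and deep libraries are not. Protein-coding genes of chromosomes 6, 7, 13 and 17 were shifted down as groups, with median log2 fold changes of -0.32, -0.30, -0.41 and -0.28. In each of the 5 knockout libraries the medians of these chromosomes lay below those of the parental libraries. Genes of chromosome 10, where CCAR1 lies, were shifted less, with a median of -0.18 and knockout libraries at -0.20 to -0.15. Chromosomes 6, 7, 13 and 17 carry 17.5% of the protein-coding genes tested and 39.3% of those called lower. Falls of named genes on these chromosomes include this shift. With the chromosome median subtracted, log2 fold changes went from -0.82 to -0.50 for FANCE and from -0.67 to -0.39 for RAD51D. Those of EFTUD2, BUD31 and MCM3 went from -0.62 to -0.34, from -0.50 to -0.20 and from -0.72 to -0.395.

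**Figure D2:**
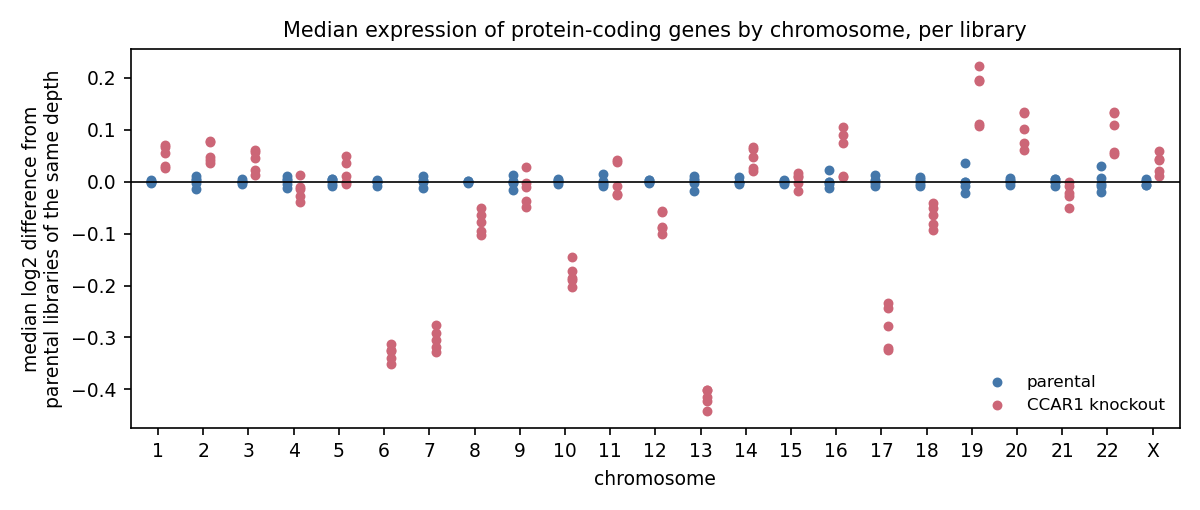
Median over the protein-coding genes of each chromosome of the log2 difference between a library and the mean of the parental libraries of the same depth; each point is a library. The 5 knockout libraries lie between -0.44 and -0.23 on chromosomes 6, 7, 13 and 17.

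Among genes with at least 2 CPM in 1 genotype and ranges apart, the largest changes were in genes under 1 CPM in the other. FRMPD4, a synaptic scaffold protein, fell from 31.8 ± 4.85 to 0.255 ± 0.0506 CPM, or 127-fold. NRXN3, a presynaptic adhesion molecule, fell 56.6-fold, from 6.47 ± 0.688 to 0.115 ± 0.0179 CPM. The desmosomal genes DSC3 and PKP2 fell 52.1-fold and 49.8-fold, from 34.2 ± 8.53 to 0.646 ± 0.0778 CPM and from 28.6 ± 2.46 to 0.616 ± 0.268 CPM. LGR5, a receptor that strengthens Wnt signalling, fell 43.5-fold from 9.19 ± 1.09 CPM, and ARAP2, ANO2 and PRSS12 fell 45.9-fold, 44.7-fold and 36.0-fold. Among the largest rises, PDE1A, a calcium-dependent phosphodiesterase, went from 0.111 ± 0.103 to 13.1 ± 2.05 CPM, or 95.2-fold. ENTREP2 and PCDHB8, a clustered protocadherin, each rose 105-fold, to 2.51 ± 0.249 and 8.32 ± 0.973 CPM. The potassium channel subunit KCNG1 rose 63.1-fold to 9.26 ± 1.99 CPM, the cancer-testis gene MAGEA11 62.0-fold to 2.98 ± 0.260 CPM, WDR87 49.3-fold, the collagen gene COL14A1 48.8-fold to 8.44 ± 0.921 CPM, and HLA-DPA1, an MHC class II chain, 44.7-fold to 6.14 ± 0.419 CPM. For these 16 genes the parental and knockout ranges were apart, and the largest edgeR adjusted p was 2.54e-05. The genes that rose had 21 to 166 counts in all parental libraries together, so the size of their folds is imprecise. PCDHB8 and HLA-DPA1 belong to families of similar genes, between which reads can be shared.

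**Figure D3:**
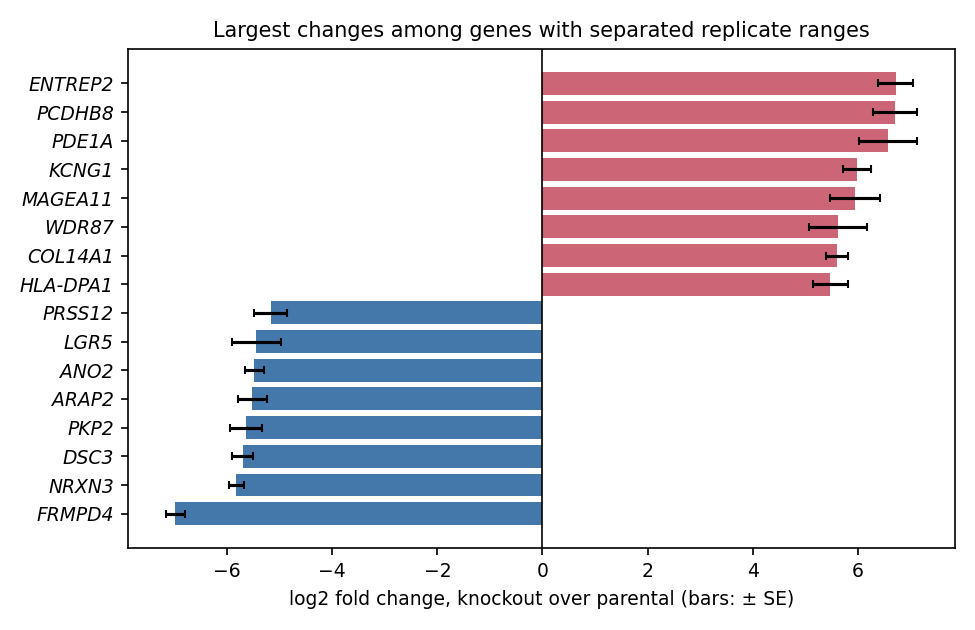
Log2 fold change (knockout over parental) of the 8 genes that fell most and the 8 that rose most under the naming rule. That rule asks for at least 2 CPM in either genotype and no overlap between the genotypes. Bars show ± the standard error of the edgeR fit. The folds run from 127-fold lower for FRMPD4 to 105-fold higher for ENTREP2 and PCDHB8.

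RNA-binding proteins that choose splice sites, the SR and hnRNP group, were lower as a list: 23 of 56 measured members fell, 5 rose and 28 did not pass, with the same counts adjusted over the list alone. HNRNPH3 fell from 452 ± 9.67 to 255 ± 13.8 CPM, and the neuronal splicing factor NOVA1 from 8.29 ± 0.381 to 4.37 ± 0.519 CPM. RBM10 and SRSF5 rose 1.38-fold and 1.23-fold, to 170 ± 20.1 and 206 ± 10.9 CPM. The median log2 fold change was -0.19, with -0.17 in the shallow and -0.26 in the deep libraries (camera adjusted p = 0.00412, and adjusted p = 0.270 with an estimated correlation). With the replicate block 9 rose and 36 fell. Of 51 core spliceosome genes 11 fell and 0 rose in the edgeR test, adjusted over the list alone as well, while 2 rose and 16 fell with the block, and the list did not pass (camera adjusted p = 0.0726). The core spliceosome list test passed in the deep libraries alone (38 lower, 3 higher, camera adjusted p = 5.79e-05), with chromosome medians subtracted (0.0156), and without parental replicate 2 (0.0448), knockout replicate 2 (0.0345) or knockout replicate 3 (0.0411). It did not pass in the shallow libraries alone (0.171), nor over all libraries with an estimated correlation (adjusted p = 0.270, and 0.590 with the block). EFTUD2, a GTPase of the U5 particle encoded on chromosome 17, fell from 243 ± 10.8 to 158 ± 9.72 CPM, and BUD31, encoded on chromosome 7, from 80.3 ± 2.25 to 56.9 ± 4.36 CPM. The list's median log2 fold change was -0.05.

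The lists of G1/S and of mitotic genes were lower in camera with its preset correlation, and neither passed with an estimated correlation. Of their 92 genes 39 were past the threshold in either direction. Of 46 genes of the G1/S transition and DNA replication 24 fell, 2 rose and 20 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.45e-05, and adjusted p = 0.132 with an estimated correlation). MCM3, a subunit of the replicative helicase encoded on chromosome 6, fell from 289 ± 6.28 to 176 ± 5.11 CPM, and the helicase loader CDC6, on chromosome 17, from 124 ± 8.14 to 75.4 ± 3.48 CPM. The GINS subunits GINS3 and GINS4 rose 1.32-fold and 1.42-fold. Of 46 genes of G2 and mitosis 13 fell and 0 rose in the edgeR test, and 12 fell adjusted over the list alone (camera adjusted p = 0.00317, and adjusted p = 0.418 with an estimated correlation). With the replicate block 31 of them fell and 2 rose. The mitotic transcription factor FOXM1 fell from 421 ± 8.10 to 290 ± 8.001 CPM, CDCA3 from 108 ± 8.98 to 72.0 ± 7.84 CPM, the checkpoint protein BUB3 from 753 ± 19.99 to 586 ± 12.4 CPM, and BIRC5, or survivin, on chromosome 17, from 322 ± 7.35 to 242 ± 16.1 CPM. BIRC5 went from a log2 fold change of -0.41 to -0.13 with the chromosome median subtracted, which ended its call (edgeR adjusted p = 0.121). The median log2 fold changes of the G1/S list were -0.23 in the shallow and -0.29 in the deep libraries, and those of the mitotic list -0.26 and -0.24. Of 47 replication-dependent histone genes 28 were measured in these poly(A)-enriched libraries, which can miss transcripts without a poly(A) tail. Of the 28 measured 8 rose and 1 fell, and 9 rose and 2 fell with the block (median log2 fold change 0.19, camera adjusted p = 0.154). With chromosome medians subtracted, the histone list passed as higher (median 0.52, camera adjusted p = 0.00748). On chromosome 6 the median removed was -0.32, but protein-coding genes from 20 to 30 Mb there had a median of -0.0588. The subtraction can therefore raise genes of that stretch by itself, and how many of the histone genes lie there was not counted. Without the subtraction and with an estimated correlation the histone list's adjusted p was 0.692.

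Targets of YAP and TAZ, the transcriptional coactivators of the Hippo pathway, fell together: 16 of 22 fell and 1 rose, and 17 fell and 1 rose adjusted over the list alone (median log2 fold change -0.66, -0.69 in the shallow and -0.68 in the deep libraries; camera adjusted p = 7.17e-07, and adjusted p = 0.132 with an estimated correlation). CCN2, a matricellular growth factor, fell from 298 ± 22.1 to 103 ± 8.32 CPM, CCN1 from 1107 ± 33.1 to 570.0 ± 37.3 CPM and the Hippo kinase LATS2, on chromosome 13, from 32.7 ± 1.49 to 13.5 ± 1.07 CPM. IGFBP3 rose 1.15-fold. In the blocked fit 19 YAP/TAZ targets fell and 2 rose. Mesenchymal genes rose, with 15 of 24 higher and 2 lower, also when adjusted over the list alone (median 0.37, 0.41 in the shallow and 0.31 in the deep libraries; camera adjusted p = 0.00729, and adjusted p = 0.218 with an estimated correlation). SNAI2, a repressor of epithelial genes, rose from 6.44 ± 0.760 to 31.5 ± 1.296 CPM and the fibronectin receptor subunit ITGA5 from 281 ± 10.2 to 628 ± 19.1 CPM. CDH11 and ACTA2 fell 5.70-fold and 1.71-fold. Of the mesenchymal genes 15 rose and 5 fell with the block.

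Of 19 epithelial junction and keratin genes 7 fell and 2 rose, and 10 fell and 2 rose adjusted over the list alone (median -0.30, -0.41 in the shallow and -0.44 in the deep libraries). Desmoplakin, DSP, on chromosome 6, fell from 71.3 ± 6.47 to 18.2 ± 2.58 CPM, PKP3 rose from 5.74 ± 1.27 to 10.6 ± 2.59 CPM, and CDH3 rose at a low level, from 0.0273 ± 0.0155 to 0.221 ± 0.0539 CPM. The camera adjusted p was 0.0428, with adjusted p = 0.418 with an estimated correlation. It was 0.0644 with the replicate block (3 higher, 11 lower), 0.0526 with DESeq2 size factors, and 0.0566, 0.0528 and 0.0557 without parental replicates 1, 2 and 3. Of 42 interferon response genes 15 rose, 1 fell and 26 did not pass, and 19 higher and 2 lower adjusted over the list alone (median 0.31, 0.39 in the shallow and 0.21 in the deep libraries). OASL rose from 0.629 ± 0.0860 to 3.59 ± 0.857 CPM, IFI44 from 2.14 ± 0.383 to 5.85 ± 0.504 CPM and SAMD9 from 0.648 ± 0.109 to 3.44 ± 1.196 CPM, and HERC5 fell from 7.83 ± 1.40 to 4.90 ± 0.742 CPM. Its camera adjusted p was 0.0374, with adjusted p = 0.471 with an estimated correlation. It was 0.0572 with the replicate block (23 higher, 9 lower), 0.0538 with a filter of 1 CPM in 5 libraries, 0.0545 in limma-voom, 0.0520 without knockout replicate 1 and 0.169 in the deep libraries alone.

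**Figure D4:**
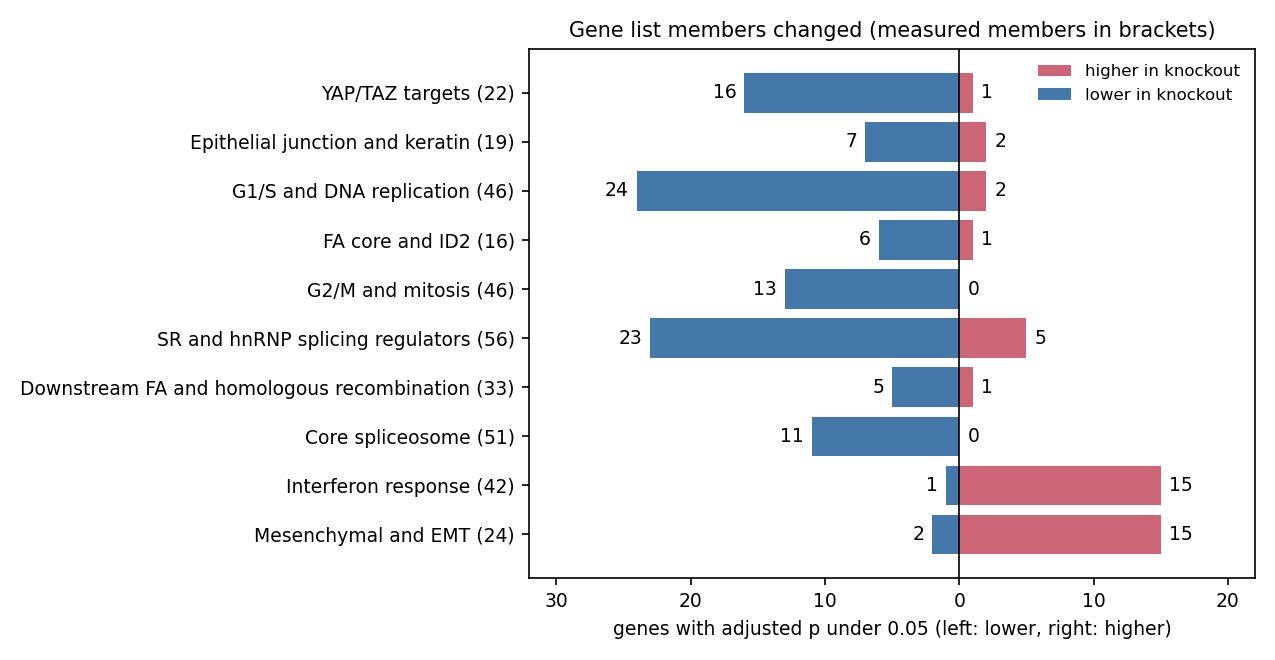
Number of genes in each list with edgeR adjusted p under 0.05, with bars to the left for lower and to the right for higher in knockout cells and the number of measured members in brackets. The YAP/TAZ list has 16 lower and 1 higher gene of 22, and the interferon list 15 higher and 1 lower of 42.

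Only 7 of the 37 lists passed camera without the block. With the replicate block the checkpoint kinases (13 lower, 1 higher of 18 in that fit, camera adjusted p = 0.0219), TGF-beta targets (13 higher, 4 lower of 20, camera adjusted p = 0.0407) and cytosolic ribosomal proteins (45 higher, 6 lower of 75, camera adjusted p = 0.0146) passed as well, each losing the call with an estimated correlation (adjusted p = 0.387, 0.387 and 0.793). Without the block these lists had 4 lower and 0 higher, 8 higher and 3 lower, and 5 higher and 2 lower genes in the edgeR test. The ribosomal list rose mainly in the shallow libraries, with a median log2 fold change of 0.26 (37 higher, 4 lower, camera adjusted p = 8.59e-04). In the deep libraries alone it did not pass, with a median of 0.0477 (20 higher, 13 lower, camera adjusted p = 0.709). The checkpoint kinases list test also passed without parental replicate 1 (0.0499), 2 (0.0447) or 3 (0.0439) and without knockout replicate 4 (0.0277) or 5 (0.0291). Without knockout replicate 4 or 5 the TGF-beta targets list test (0.0494 and 0.0359) and the cytosolic ribosomal proteins list test (0.0164 and 0.0192) passed as well. Over all libraries without the block, the adjusted p of these lists with an estimated correlation was 0.673, 0.471 and 0.830. Of 29 measured p53 targets 4 rose and 10 fell in these p53-null cells (camera adjusted p = 0.128). Of 16 measured retinal pigment epithelium genes 7 rose and 1 fell, and 8 rose and 3 fell with the block (camera adjusted p = 0.151 without it).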

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

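The tests of depth, of chromosome windows, of BRCA1, of paralog reads and of the tissue transcripts were chosen after the results they measure were seen. The comparison of erythroid and liver genes with all other genes replaced a first bound of 80% that was not met. Of 114 groups of 5 libraries, 5.7 would have a library far from the rest by chance at a rate of 1 in 20. 4 groups had such a library. FANCA in knockout replicate 3 stood at 53.8 CPM against 49.5 CPM in the next library, a gap of 0.833 of the group's range. ITGA5 stood at 299 against 279 CPM in parental replicate 1 (gap 0.789) and at 662 against 622 CPM in knockout replicate 1 (gap 0.920). ENTREP2 was at 0 CPM in parental replicate 2 and 0.0177 CPM in the next library (gap 0.716). All 4 lie within a genotype and are small beside the difference between genotypes.

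The effect of the knockout differed between the deep and the shallow libraries for 114 of 18979 genes in an edgeR interaction test. Among the named genes, PKP2 fell more in the deep libraries (interaction -1.39, adjusted p = 0.00266), with log2 fold changes of -5.09 and -6.50 in the shallow and deep libraries. LGR5 did likewise (interaction -2.01, adjusted p = 0.0224; -4.68 and -6.72).

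Genes on chromosomes 6, 7, 13 and 17 were lower as groups, and 95.9% of the 49 windows of 10 Mb on them had a median below -0.15, against 10.7% of 242 windows elsewhere, where chromosome 10 had 8 of 14 and chromosome 8 had 6 of 15 below it. Bias from GC content or gene length is argued against, since 108% of the mean of these medians was left with both regressed out, and so is depth, since the mean in the shallow libraries was 86.7% of that in the deep ones. A candidate explanation is a difference in copy number of whole chromosomes between the parental and the knockout cells: if RNA followed DNA, a change from 4 copies to 3 would give -0.42 and from 2 to 1 would give -1, while chromosome 13 was at -0.41 and chromosomes 6, 7 and 17 at -0.32, -0.30 and -0.28, so the number of copies is left open. The shift of a gene's own window did not account for most changes beyond 0.58. Of 3826 called genes of that size, 82.8% stayed beyond 0.58 with the median of their window subtracted. A high share was likely, since few windows of the other chromosomes were shifted. Effects of a copy-number difference on genes elsewhere in the genome were not tested. Smaller changes, nearer the size of the shifts, were not covered by this test. With chromosome medians subtracted 3794 genes were called higher and 2556 lower, against 3741 and 3198 without. Loss of a copy of the region around FANCA is argued against by its 38 neighbours within 2 Mb, whose median was 0.0621 ± 0.11 (standard error). A loss of FANCA alone, or an indirect effect of the shifted chromosomes on it, was not tested. FANCA's own fold change was -0.71 or beyond at each depth. With depth as a term and the chromosome 17 median subtracted BRCA1 stayed at -0.31 ± 0.040, so its whole fall was not accounted for. DNA was not measured, and whether a difference in copy number, if present, came with the loss of CCAR1 or with the derivation of the line stays open.

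The protocadherin beta genes of chromosome 5 rose nearly as a block: 13 of 14 measured were higher, with a median log2 fold change of 3.68, and their summed level went from 4.64 ± 0.567 to 60.2 ± 6.31 CPM (exact permutation p = 0.00794, n = 5, the smallest 252 arrangements can give). Reads exchanged between paralogs alone would leave that sum in place, but it rose by 3.70 ± 0.10 (standard error) on the log2 scale. A gained copy of the region is argued against by the 46 neighbours within 2 Mb, whose median was 0.0726 ± 0.074. PCDHB1 did not rise (0.512 and 0.491 CPM). Of 19 gamma genes 13 rose, but their summed level rose less, from 171 ± 3.24 to 244 ± 8.8 CPM, or 0.515 on the log2 scale. What raised these genes was not tested further.

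Transcripts of skeletal muscle, red blood cells and liver stood in all 6 shallow libraries, with MYH7 at 32.3 to 136 CPM, ACTA1 at 63.3 to 157 CPM, HBA1 at 15.9 to 60.2 CPM and ALB at 8.16 to 31.5 CPM, while in the 4 deep libraries these were at most 0.156 CPM. A muscle-like state of the cells is argued against, since 62.5% of the 32 detected erythroid and liver genes (exact 95% interval 43.7 to 78.9%) were at least 10-fold higher in the shallow libraries, against 1.76% of all other genes. Genotype is argued against for the shallow libraries, where the knockout had 89.6% of the parental sum with overlapping ranges of 725.1 to 1028 and 835.8 to 1168 CPM, but not for the low levels in the deep libraries, where the knockout sums of 37.7 and 38.5 CPM lay above the parental 19.5 and 20.9 CPM. The deep sums rest largely on TNNT1, with a mean of 16.8 CPM there and only 3-fold more in the shallow libraries. The gap between genotypes in the deep libraries need not hold for the tissue genes as a set. RNA of other tissues is a candidate source that the test left open, since 93.3% of the muscle but 58.3% of the erythroid and 65.0% of the liver genes were 10-fold higher, where 80% of each was asked. Of the 62 detected genes 4 had a mean of at least 1 CPM in the deep libraries, and the source of the RNA was not identified.

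Regrouping the libraries did not give as many changed genes. Among 100 of the 126 splits of the libraries into 5 and 5, only 1, the real split, gave as many genes: 3741 higher and 3198 lower, where the other splits reached 2292 in a single direction, and 2004 changed at least 2-fold, where they reached 447. The highest other counts came from splits that put all 4 deep libraries together (up to 4294 genes), and the other 47 with 2 deep libraries on each side gave 0, as did the 9 of them that part all 5 pairs. With depth as a term, 1 of 60 splits even in depth, the real split, gave 12149 genes and the other splits at most 0 in edgeR. Every other split holds both genotypes on each side, so the difference between genotypes adds to the spread within its groups. Low counts were therefore likely, and they do not tell what made the genotypes differ.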

How the results depend on the processing

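The settings with depth as a term, a single depth, thinned libraries or chromosome medians were chosen after the data were seen. No result changed direction with a call under any setting. FANCA passed in every setting, from -0.65 to -0.76. Leaving out each library moved the CCAR1 log2 fold change between -0.56 and -0.42 and lost its call without parental replicate 5 (adjusted p = 0.0504). The call was also lost with library size only (-0.42) and with chromosome medians subtracted (-0.31, adjusted p = 0.121), though with depth as a term as well the adjusted p was 1.60e-06. The cause was not tested.

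The replicate block raised the counts to 5906 higher and 5713 lower, depth as a term to 6200 and 5949, and depth with chromosome medians to 6359 and 5371. Replicates 1 to 3 alone gave 4931 lower, and replicates 4 and 5 alone 7775 higher, 7545 lower and 3707 changed at least 2-fold, with more genes tested. A filter of 1 CPM in 5 libraries left 1121 changed at least 2-fold of 13655 tested. With the deep libraries thinned 6625 genes were called, within 1.5 times of 6939, so depth alone does not set the count.

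The Fanconi anemia core list passed with no filter (adjusted p = 0.00537), the DESeq2 test (0.0131), the replicate block (0.0487), depth as a term (0.0388), the deep libraries alone (0.0075), chromosome medians subtracted (0.0449), both (0.0299) and fry (2.48e-07). With an estimated correlation its adjusted p was 0.270, 0.387 with the block and 0.316 with depth as a term. The homologous recombination list passed with no filter (0.00639), the DESeq2 test (0.0323), the block (0.0196), depth as a term (0.0142), the shallow (0.0122) and the deep (0.00256) libraries alone and depth with chromosome medians (0.00869), and ran from 0.0292 to 0.150 with each library left out. With an estimated correlation it was at 0.692, and 0.563 with the block. Of the 35 other lists 7 passed, against 23 with no filter, 15 in the DESeq2 test, 15 in the deep libraries, 12 with depth and chromosome medians, 26 in fry and 0 with an estimated correlation. Apart from the calls given with their results, the block changed no other call among the named genes and lists with values given here. The cause of these differences was not tested.

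Among other named genes, FANCC lost its call with library size only or no filter, FANCL with library size only or without parental replicate 4 or 5, FAAP24, RAD51B and IGFBP3 with no filter, and FAAP24 and BIRC5 with chromosome medians subtracted. Low counts limit the folds of genes near 0 CPM.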

Other observations

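Several groups outside the lists that passed held large changes, and these genes and the families of the next paragraph were chosen after their values were seen. THBS1, a matrix glycoprotein, fell from 208 ± 44.3 to 37.8 ± 10.7 CPM (edgeR adjusted p = 1.16e-05), and the Wnt antagonist DKK1 from 292 ± 10.0 to 97.5 ± 5.16 CPM (2.13e-08). HMOX1, which degrades heme, rose from 16.5 ± 1.16 to 87.9 ± 7.10 CPM (1.29e-08), the carbonic anhydrase CA9 from 0.268 ± 0.0340 to 2.14 ± 0.549 CPM (2.36e-06) and the alarmin IL33 from 0.0793 ± 0.0320 to 2.74 ± 0.529 CPM (3.93e-07), each with n = 5.

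MHC class II genes rose from near 0: 6 of 9 genes of this group were higher, and their summed level went from 2.64 ± 1.63 to 20.9 ± 4.4 CPM (exact two-sided permutation p = 0.00794, n = 5, the smallest 252 arrangements can give). HLA-DRA went from 0.0938 ± 0.0711 to 1.83 ± 0.379 CPM and HLA-DMA from 0.391 ± 0.0569 to 3.12 ± 0.425 CPM. The log2 fold change of HLA-DRA was 3.83 in the shallow and 6.18 in the deep libraries, that of HLA-DPB1 1.88 and 4.00 and that of HLA-DMA 3.03 and 2.88, so the size of the rise is uncertain for some of them. CIITA, the master regulator of these genes, rose from 3.63 ± 0.461 to 10.4 ± 0.713 CPM (edgeR adjusted p = 1.49e-06). Of 9 measured immune cell markers, which include red cell genes, 3 rose and 0 fell in edgeR, and 4 rose and 1 fell with the replicate block (median log2 fold change 0.73, camera adjusted p = 0.162). CSF1R went from 1.65 ± 0.159 to 6.32 ± 0.572 CPM, CD68 from 41.1 ± 4.86 to 72.7 ± 9.49 CPM and CD4 from 0.340 ± 0.150 to 0.946 ± 0.0851 CPM, while PTPRC, a marker of white blood cells, was at 0.455 ± 0.313 and 0.3202 ± 0.325 CPM (edgeR adjusted p = 0.695, and 0.0493 with the block). Whether a few cells of another type add to the class II rise was not tested. HLA-B and HLA-C, which are class I genes, had edgeR adjusted p-values of 0.716 and 0.724.

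HNRNPH3, the hnRNP gene with the smallest adjusted p, lies at 68331174 to 68343191 on chromosome 10, less than 1 Mb from CCAR1. The 32 protein-coding neighbours of CCAR1 within 2 Mb had a median log2 fold change of -0.21 ± 0.088 (bootstrap standard error), with 9 lower and 5 higher, against -0.82 for HNRNPH3 and -0.48 for CCAR1.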
